A study of Homo sapiens with 15 samples.

How the data were processed

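Poly(A)-selected, strand-specific libraries from 15 samples of HepG2 cells were sequenced as 150 bp paired-end reads on an Illumina NovaSeq, per the labels' protocols, after a check of RNA integrity (minimum RIN 7.0). The authors deposited 1 matrix of raw read counts per gene symbol for all 15 libraries. The submitters' processing notes name HISAT2 and HTSeq without versions, DESeq2 1.46.0 and R 4.4.2, and the genome build GRCh38. The annotation release, the strand setting of the counting and the rule behind the filtering of the matrix are not given in the sources used here. Because the strand setting is not stated, genes that overlap on either strand are uncertain, as are paralogs and pseudogenes whose reads could be split or dropped. The matrix held 41412 rows, of which 14176 were 0 in every library, and no row was a total or other non-gene row. Rows that shared a symbol (1330) were kept apart. No row for the transfected reporter was analysed here, so uptake and translation of the mRNA were not measured.

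Columns were matched to samples by the library names in the labels. The groups and replicate numbers came from the sample titles, which state that replicates are biological. Replicate pairs of every group differed by far more than sampling noise, so all 15 libraries were counted as separate samples. Library totals ran from 57128519 to 78548789 counts. At this depth counting error is small for most tested genes, and the spread between replicates sets the precision: the biological coefficient of variation was 0.344, and the median 95% interval of a log2 fold change between groups of 3 reached 0.62 to either side.

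Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Low genes were removed with filterByExpr at its defaults, leaving 18380. Libraries were scaled by TMM, dispersions were estimated robustly, and a quasi-likelihood model with 1 mean per group was fitted to all 15 libraries, so that every comparison shared 1 estimate of spread. The comparisons were each transfected group against untransfected cells, the mean of the 4 transfected groups against untransfected cells, each cloaked group against the non-cloaked group, strong against weak cloaking, an F test of any difference among the 4 transfected groups, and a linear trend over the 4 grades. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The standard error of a log2 fold change was taken from its size and the F statistic.

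Before the data were examined, 28 gene lists were fixed, covering innate immunity, stress responses, lipid and liver metabolism, growth, RNA quality and markers of other cell types. They were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and members were also adjusted over each list alone. The rule for naming genes was fixed at the same time: the 8 largest increases and 8 largest decreases among called genes with a mean log2 CPM of at least 1 and no overlap between replicates of the 2 sides, up to 4 called members per list, up to 10 interferon-stimulated genes, and the 5 genes of smallest p (8 for the F test) where fewer than 5 were called. Some genes that meet this rule are not reported here. Weak-cloaked replicate 1 and genes with 8-fold differences between replicates (100 or more counts in the higher library) were singled out after their values were seen. Gene positions, transcript lengths and GC content came from GENCODE release 29 on GRCh38, the build the submitters name, which annotated 36466 rows of the matrix by symbol, a further 3494 by identifier, and 18246 tested genes (99.3%).

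The alternatives were DESeq2 1.42.0, RLE size factors, no filter, a filter of 50 counts in 3 libraries, the replicate number as a block, non-robust estimation, a fit of the compared groups alone, and leaving out each library in turn. Added after the data were seen were offsets for transcript length and GC content (a loess fit in each library, also run with the replicate block), total-count scaling, and the removal of genes that switched between replicates. The procedure was tested on simulated data with the real means, library sizes and dispersions. Changes were placed only in genes with a mean log2 CPM of at least 1, so recovery among lower genes was not tried. In non-cloaked against untransfected cells, over 18380 genes, it recovered 2 of 67 genes changed 1.5-fold (3.0%), 30 of 67 changed 2-fold (44.8%) and 58 of 66 changed 4-fold (87.9%). In strong-cloaked against non-cloaked cells it recovered 4, 20 and 52 of them (6.0%, 29.9% and 78.8%). False calls numbered 5 of 95 and 4 of 80. Overlap between comparisons that share the untransfected libraries was simulated 20 times with no effect.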

Results

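RNA was sequenced from HepG2 cells, an established human hepatocellular carcinoma line, in 5 groups of 3 biological replicates. One group was left untransfected. The other 4 groups received 1 µg of mRNA coding for enhanced green fluorescent protein in lipid nanoparticles, and all cells were lysed 48 h later. The mRNA was either non-cloaked or had been treated with a reagent named CR-3 at 3 grades, called weak (0.1 M for 0.5 h at 25 °C), medium (0.5 M for 1 h at 30 °C) and strong (1 M for 2 h at 37 °C). The series states its purpose as measuring what cloaking of the mRNA does to gene expression across the transcriptome. No group received particles without mRNA, so the comparisons with untransfected cells cover particle and mRNA together. Library totals ran from 57128519 counts (weak-cloaked replicate 1) to 78548789 (strong-cloaked replicate 1), and 18380 genes had enough counts to be tested.

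The largest axis of variation among libraries separated the untransfected cells from the transfected ones. It held 21.1% of the variance in a principal component analysis, with the untransfected libraries between -70.5 and -68.6 and 11 transfected libraries between -7.8 and 44.1. Weak-cloaked replicate 1 stood apart from its group at -51.6, near the untransfected libraries. The 4 transfected groups were interspersed on this axis.

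**Figure D1:**
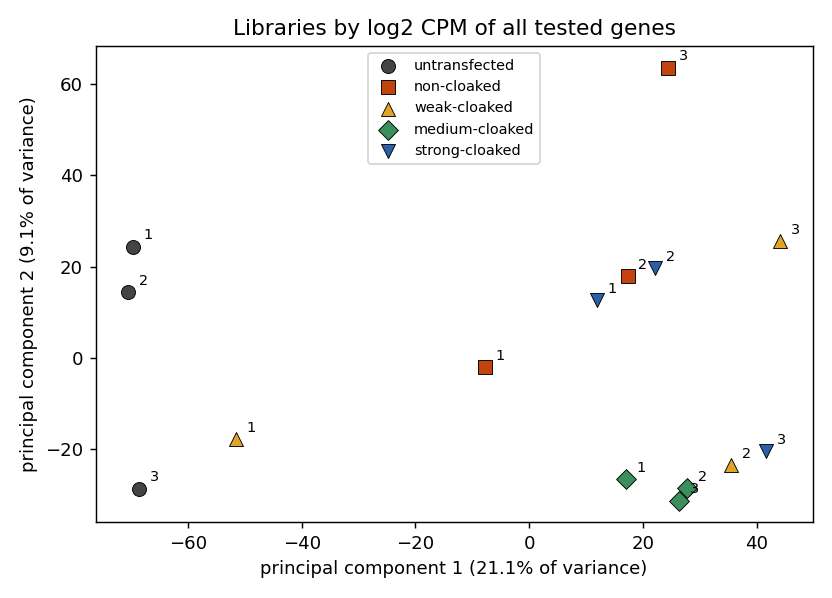
Principal components 1 (21.1% of the variance) and 2 (9.1%) of log2 CPM (counts scaled to library size) over the tested genes. Each point is 1 library, coloured by group and numbered by replicate. Untransfected libraries lie at the left, weak-cloaked replicate 1 lies near them at -51.6 on component 1, and the other transfected libraries lie from -7.8 to 44.1.

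Transfection as such was examined by setting the mean of the 4 transfected groups against the untransfected group. G6PC1, the catalytic subunit of glucose-6-phosphatase in gluconeogenesis (ENSG00000131482, chromosome 17, 42900797 to 42913369 on GRCh38), fell from 42.8 ± 3.54 CPM (SD, n = 3) in untransfected cells to between 4.28 ± 1.45 and 5.91 ± 2.21 CPM in the 4 transfected groups. FST, which encodes the activin-binding protein follistatin (chromosome 5, 53480409 to 53487134), fell from 53.9 ± 25.3 CPM to 8.95 ± 1.05 in non-cloaked and 11.2 ± 3.03 in weak-cloaked cells. SLAMF9, a member of the SLAM family of immune receptors (chromosome 1, 159951492 to 159954254), rose from 0.62 ± 0.475 CPM to between 5.71 ± 0.958 and 7.6 ± 3.07. KRTAP3-1, a keratin-associated protein gene (chromosome 17, 41008521 to 41019324), rose from 4.84 ± 1.13 CPM to between 27.8 ± 4.65 and 40.5 ± 19.3. In log2 terms these changes were -3.11 ± 0.22 (SE) for G6PC1, -2.36 ± 0.20 for FST, 3.39 ± 0.49 for SLAMF9 and 2.86 ± 0.29 for KRTAP3-1, with adjusted p of 1.8e-05, 4.3e-05, 0.0011 and 0.00019 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The other largest increases were in C19orf53 (3.76 ± 1.25), the glucose transporter gene SLC2A10 (2.90 ± 0.72), the pseudogene HSD17B7P2 (2.80 ± 0.59), the mast-cell tryptase gene TPSAB1 (2.46 ± 0.25), the stress-responsive kinase gene PLK3 (2.30 ± 0.40) and the MAP kinase phosphatase gene DUSP1 (2.23 ± 0.39). TPSAB1 and HSD17B7P2 have near-identical relatives, so their counts are uncertain. The other largest decreases were in ZNF362 (-3.14 ± 0.54), EDN1, the gene of the vasoconstrictor endothelin-1 (-2.74 ± 0.53), PIP5K1C (-2.35 ± 0.70), the DNA helicase gene PIF1 (-2.32 ± 0.58), HPS6 (-2.31 ± 0.48) and MOCS3 (-2.28 ± 0.42). Counts of C19orf53, ZNF362, EDN1, PIP5K1C and PIF1 differed 8-fold or more between replicates of at least 1 group with 100 or more counts in the higher library. SLC2A10 (6 to 87 counts) and SLAMF9 (11 to 94 counts) differed as much between untransfected replicates at lower counts. The gene C19orf53 lost its call with the replicate number as a block (adjusted p = 0.068) and with each untransfected replicate left out (0.13 to 0.14), by the same quasi-likelihood test.

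This comparison called 4242 genes at an adjusted p below 0.05 by edgeR's quasi-likelihood test, 1906 higher and 2336 lower, and 1166 of them changed by 2-fold or more. With libraries scaled by total counts instead of TMM factors the median log2 fold change over all tested genes moved by -0.225, and the share of calls that were higher went from 44.9% to 17.8% (945 of 5303). All changes here are therefore relative to the bulk of tested genes. Without untransfected replicate 1, 2 or 3 the count was 2461, 2148 or 2779.

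Several growth-factor and stress-response transcripts rose, as measured over gene lists fixed before the data were examined. Of 26 immediate early genes, 14 rose and none fell (15 adjusted over the list alone), among them DUSP1, the transcription factor genes ATF3 (1.68 ± 0.30) and KLF6 (1.65 ± 0.30), and FOSB (1.62 ± 0.49), a subunit of AP-1. The list's median log2 fold change was 0.75, with camera's adjusted p = 9.9e-07 at a preset correlation of 0.01 and adjusted p = 0.22 with an estimated correlation. Of 25 p53 targets, 7 rose and 2 fell (8 and 2 adjusted over the list alone), led by PLK3, the growth-arrest gene GADD45A (1.85 ± 0.30), PLK2 (1.76 ± 0.28) and the pro-apoptotic gene BBC3 (1.69 ± 0.28). Of 25 targets of ATF4, the transcription factor of the integrated stress response, 6 rose (7 rose and 1 fell adjusted over the list alone), including GDF15 (1.88 ± 0.33), PPP1R15A (1.81 ± 0.39) and DDIT3 (1.12 ± 0.24). Of 25 genes of the unfolded protein response, 13 rose and 1 fell (14 and 1 adjusted over the list alone), including the chaperone gene HSPA5 (0.76 ± 0.17), ERN1 (0.94 ± 0.29) and, in the other direction, XBP1 (-0.75 ± 0.22). Of 22 heat shock genes, 4 rose and 2 fell (6 and 2 adjusted over the list alone), with HSPA1B, which has a near-identical copy, at 1.88 ± 0.58 and DNAJB1 at 1.70 ± 0.48. In camera these 4 lists had an adjusted p of 0.0013, 0.0056, 0.0014 and 0.041 with the preset correlation, and adjusted p = 0.19, 0.19, 0.20 and 0.40 with an estimated correlation. With total-count scaling the medians of the ATF4 and heat shock lists were -0.07 and -0.02. Counting both directions, the called share of each of these lists lay near that of all tested genes, though no ATF4 target was called lower. In weak-cloaked replicate 1 the immediate early list reached 0.22 (95% bootstrap interval over its genes 0.08 to 0.34) of the shift seen in the non-, medium- and strong-cloaked groups, both taken against the same 3 untransfected libraries, and the heat shock list reached -0.01 (-0.30 to 0.24). Untransfected libraries, each set against the other 2, reached -0.19 to 0.26 for immediate early genes and -0.53 to 0.44 for heat shock. Neither share of weak-cloaked replicate 1 lay outside these ranges. The baselines are not alike, since the controls also define the shift and were 2 here against 3 for weak-cloaked replicate 1. The ranges are therefore only a rough guide. With the length and GC offsets the p53 median fell from 0.32 to 0.14, while 10 p53 targets were called higher and 1 lower in place of 7 and 2.

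Several transcripts of metal handling, oxidant defence and cholesterol supply also rose. Of 14 metallothionein and metal-response genes, 7 rose and 1 fell (8 and 3 adjusted over the list alone), led by the metal-binding genes MT1A (2.09 ± 0.27), MT1X (1.48 ± 0.17) and MT2A (1.14 ± 0.18), whose sequences are similar enough that reads could be shared, while the manganese and zinc exporter gene SLC30A10 fell (-1.5 ± 0.33). Camera gave this list an adjusted p of 0.00032 with the preset correlation and adjusted p = 0.049 with an estimated correlation, the only list of this comparison to pass both. Of 27 targets of NRF2, the regulator of oxidant defence, 9 rose and 2 fell (12 and 2 adjusted over the list alone), with OSGIN1 at 1.29 ± 0.30, the ferritin light chain gene FTL at 1.00 ± 0.15 and PIR at 0.82 ± 0.18. Of 26 cholesterol synthesis genes and SREBP2 targets, 12 rose and none fell (12 and 1 adjusted over the list alone), with the sterol enzyme genes MSMO1 at 1.36 ± 0.26 and DHCR7 at 0.84 ± 0.14. Of 35 lysosome and autophagy genes, 12 rose and 2 fell (17 and 3 adjusted over the list alone), with TFE3 at 0.75 ± 0.20, the cathepsin gene CTSD at 0.69 ± 0.14 and NPC2 at 0.51 ± 0.12. Of 30 hypoxia and glycolysis genes, 8 rose and none fell (8 adjusted over the list alone), with the carbonic anhydrase gene CA9 at 1.2 ± 0.20, ALDOA at 0.99 ± 0.20, HK1 at 0.77 ± 0.19 and GAPDH at 0.70 ± 0.13. The last 4 lists had an adjusted p in camera of 0.00026, 3.2e-05, 0.0011 and 0.00064 with the preset correlation, and adjusted p = 0.23, 0.20, 0.24 and 0.38 with an estimated correlation.

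Cytosolic ribosomal protein transcripts rose by a small amount in 30 of 36 cases, and 14 of 29 DNA replication transcripts fell. Of 36 ribosomal protein genes, 30 rose and none fell (32 adjusted over the list alone), with a median of 0.43 and RPL35 (0.56 ± 0.12), RPS28 (0.53 ± 0.12), RPS19 (0.53 ± 0.11) and RPL38 (0.49 ± 0.10) as examples. Their many pseudogenes could share reads with them. Of 29 DNA replication genes, 14 fell and 1 rose (16 and 3 adjusted over the list alone), with the primase gene PRIM1 at -1.30 ± 0.27, the chromatin assembly gene CHAF1A at -1.18 ± 0.17, UHRF1 at -0.85 ± 0.12 and FEN1 at -0.58 ± 0.13. Tested with camera, the adjusted p was 4.2e-13 for ribosomal protein genes and 0.00026 for DNA replication with the preset correlation, and adjusted p = 0.25 and 0.16 with an estimated correlation. Weak-cloaked replicate 1 reached -0.04 (-0.41 to 0.25) of the ribosomal protein shift and 0.39 (0.28 to 0.53) of the replication shift. Untransfected libraries, again on an unlike baseline, reached -0.09 to 0.44 and -0.09 to 0.35. Of 30 mitotic cell cycle genes, 3 rose and 5 fell (3 and 7 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.52). KIF11 (-1.12 ± 0.26) and HMMR (-0.97 ± 0.30), a motor protein gene and a hyaluronan receptor gene, had the largest decreases.

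Fold changes followed transcript length and base composition. The 4562 genes with the shortest transcripts (longest annotated transcript up to 1964 nt) had a median log2 fold change of 0.16, and the 4562 with the longest (4982 nt or more) had -0.22. The 4562 genes of lowest GC content had a median of -0.30, and the 4562 of highest GC content 0.13. Genes called higher had a median transcript of 2424 nt and 54.0% GC, and genes called lower 4114 nt and 45.4% GC. The rise of ribosomal protein genes and the fall of long, low-GC transcripts move with this trend. With offsets for length and GC, chosen after the data were seen, 4391 genes were called, and 3397 of the original calls (80.1%) were called again with the same sign.

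Interferon-stimulated transcripts did not shift in a common direction. Of 40 measured interferon-stimulated genes, 9 rose and 9 fell (11 and 12 adjusted over the list alone), and camera's adjusted p was 0.71 (adjusted p = 0.70 with an estimated correlation). Of all 18380 tested genes 1906 were called higher and 2336 lower, a smaller share in each direction than in this list. Camera tests for a shift in a common direction and cannot register a list that moves both ways. The antiviral modifier gene ISG15 rose from 27.1 ± 1.28 CPM (SD, n = 3) to 57.2 ± 9.49 in the non-cloaked group and 62.5 ± 0.392 in the strong-cloaked group, a change of 0.99 ± 0.13 (SE) on the log2 scale over the 4 groups. IFI27 (0.83 ± 0.15), OAS1 (0.77 ± 0.11), IFITM2 (0.63 ± 0.12) and IFITM1 (0.60 ± 0.13) rose as well. The dynamin-like GTPase gene MX1 fell from 3.83 ± 0.224 CPM to 1.96 ± 0.601 and 1.5 ± 0.665 in the same groups (-1.31 ± 0.25), and DTX3L (-0.89 ± 0.20), PLSCR1 (-0.59 ± 0.14), MX2 (-0.53 ± 0.11) and PARP12 (-0.51 ± 0.13) fell. Of 23 genes of RNA sensing and signalling, 9 fell and 1 rose (10 and 1 adjusted over the list alone). DDX58, which encodes the RNA sensor RIG-I, fell by 1.26 ± 0.32, and the kinase gene IKBKE (-1.05 ± 0.24) and TRAF6 (-0.91 ± 0.24) were also lower, whereas DHX58, the gene of the related protein LGP2, rose by 1.60 ± 0.25. Of 25 NF-κB targets and cytokines, 5 rose and 2 fell (8 and 2 adjusted over the list alone), with the neutrophil chemokine gene CXCL8 at 1.70 ± 0.24, the NF-κB inhibitor gene TNFAIP3 at 1.06 ± 0.18 and IL32 at 0.92 ± 0.13. Of 25 antigen presentation genes and interferon gamma targets, 6 rose and 2 fell (6 and 2 adjusted over the list alone), with HLA-E at 0.57 ± 0.14 and the transactivator genes NLRC5 and CIITA at -1.04 ± 0.20 and -0.86 ± 0.23. The adjusted p from camera for the sensing, NF-κB and antigen lists was 0.015, 0.012 and 0.015 with the preset correlation, and adjusted p = 0.30, 0.16 and 0.40 with an estimated correlation. With the length and GC offsets, the sensing and antigen lists no longer passed even with the preset correlation (adjusted p = 0.064 and 0.10).

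Hepatocyte transcripts went both ways. Of 28 hepatocyte product genes, 5 rose and 5 fell (5 and 5 adjusted over the list alone), and camera's adjusted p was 0.34. The liver transcription factor genes CEBPA (-0.89 ± 0.23) and HNF4A (-0.66 ± 0.14) fell, and the asialoglycoprotein receptor gene ASGR1 rose by 0.59 ± 0.13. Of 24 acute-phase genes, 5 rose and 1 fell (6 and 2 adjusted over the list alone), with the lipopolysaccharide-binding protein gene LBP at 1.62 ± 0.42 and the protease inhibitor gene SERPINA3 at 0.88 ± 0.18, and the list did not pass camera (adjusted p = 0.15).

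Markers of RNA quality and of other cell types were examined beside these groups. Of 13 mitochondrially encoded mRNAs, 4 fell and none rose (4 and 1 adjusted over the list alone), including MT-ND3 (-0.41 ± 0.13) and MT-CO3 (-0.35 ± 0.08), which code for respiratory chain subunits, and the list did not pass camera (adjusted p = 0.39). Of 18 replication-dependent histone mRNAs, a class that mostly lacks poly(A) tails, 5 rose and none fell (5 adjusted over the list alone). H2BC21, whose longest annotated transcript has 2194 nt, was at 2.02 ± 0.41, and whether single members carry tails was not measured. The list's adjusted p in camera was 0.008 with the preset correlation and adjusted p = 0.26 with an estimated correlation. The histone median of 0.51 was 0.25 with the length and GC offsets. Among markers of cell types other than hepatocytes, 3 of 15 leukocyte markers rose and none fell (4 adjusted over the list alone), with the macrophage gene CD68 at 1.87 ± 0.40. Of 14 fibroblast and endothelial markers, 2 rose and 2 fell (2 and 2 adjusted over the list alone), with the endothelial receptor gene TIE1 at 1.5 ± 0.17 and the platelet-derived growth factor receptor gene PDGFRB at -1.42 ± 0.23. Of 15 markers of other epithelial lines, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with the trefoil factor gene TFF1 at 1.84 ± 0.46 and the keratin gene KRT17 at 1.66 ± 0.28. None of these 3 marker lists passed camera in this pooled comparison (adjusted p = 0.06, 0.52 and 0.11).

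**Figure D2:**
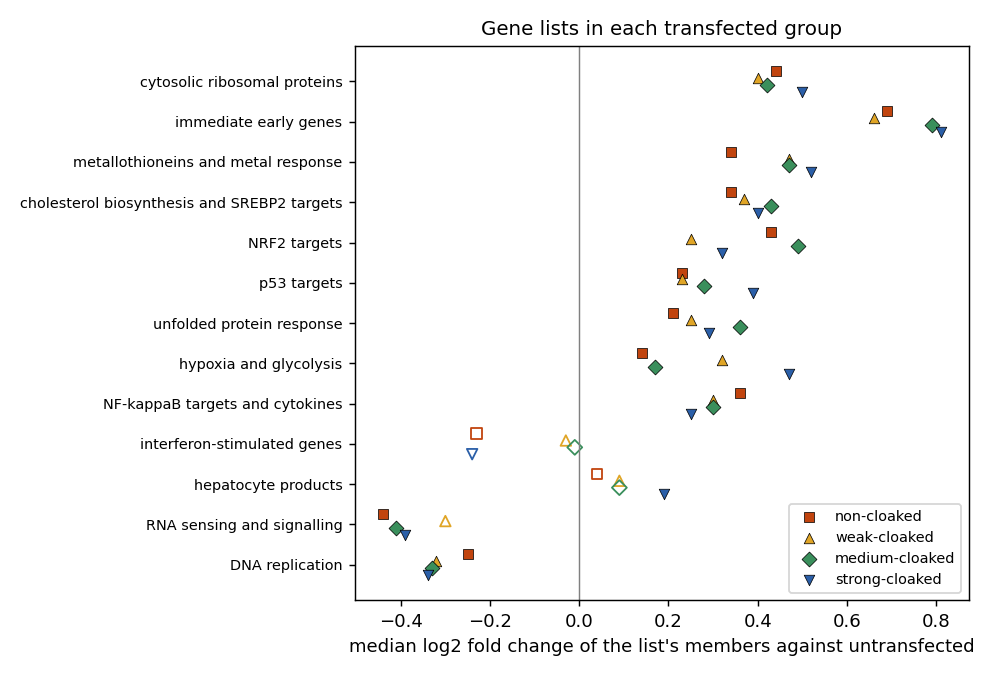
Median log2 fold change of the measured members of 13 gene lists in each transfected group against untransfected cells. Filled symbols passed camera with the preset correlation and open symbols did not. Among the 13 lists shown, immediate early genes had the highest medians (0.66 to 0.81) and the RNA sensing list was lowest in the non-cloaked group (-0.44).

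Cells given non-cloaked mRNA were compared with untransfected cells to show what unmodified transfection does. SPAG1, a gene required for the assembly of ciliary dynein arms (ENSG00000104450, chromosome 8, 100157906 to 100259278), fell from 16.1 ± 6.68 CPM (SD, n = 3) to 0.267 ± 0.0774. G6PC1 (-2.86 ± 0.35, SE), FST (-2.59 ± 0.31), ZNF587B (-2.27 ± 0.49), the ribosomal S6 kinase gene RPS6KA3 (-2.19 ± 0.50) and the centriole gene SASS6 (-2.15 ± 0.55) fell too, as did ZNF362 (-4.66 ± 0.93) and FNIP2 (-3.62 ± 0.95), whose counts were unstable between replicates. SLC2A10 (4.56 ± 0.85), SLAMF9 (3.23 ± 0.53), CKAP4, a membrane protein gene of the endoplasmic reticulum (2.99 ± 0.64), KRTAP3-1 (2.52 ± 0.32), TPSAB1 (2.51 ± 0.28), HSD17B7P2 (2.50 ± 0.65), the complement gene C2 (2.40 ± 0.64, unstable between replicates) and WNT7B (2.18 ± 0.23) rose. Of the lists, 9 of 26 immediate early genes rose and none fell (12 adjusted over the list alone), 10 of 36 ribosomal protein genes rose and none fell (29 adjusted over the list alone), and 5 of 14 metallothionein and metal-response genes rose and none fell (6 and 1 adjusted over the list alone). Their adjusted p with camera was 2.9e-07, 4.6e-12 and 0.0024 with the preset correlation, and adjusted p = 0.24, 0.25 and 0.095 with an estimated correlation. Histone mRNAs (1 of 18 higher, 4 adjusted over the list alone, median 0.86), leukocyte markers (1 of 15 higher, 2 adjusted over the list alone, median 0.56) and markers of other epithelial lines (3 of 15 higher, 4 adjusted over the list alone, median 0.29) also passed with the preset correlation (adjusted p = 0.0028, 0.036 and 0.021) and had adjusted p = 0.24, 0.24 and 0.25 with an estimated correlation. edgeR's quasi-likelihood test called 1195 genes, 706 higher and 489 lower. With total-count scaling 31.3% of calls were higher (346 of 1104) in place of 59.1%. The count was 250, 235 or 379 without untransfected replicate 1, 2 or 3, and 119 or 185 without non-cloaked replicate 2 or 3. DESeq2 called 2968.

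In cells given weak-cloaked mRNA, SPAG1 was at 11.5 ± 4.11 CPM (SD, n = 3) and was not called against untransfected cells. G6PC1 fell (-3.32 ± 0.36, SE), as did FST (-2.27 ± 0.30), the orphan nuclear receptor gene NR6A1 (-2.25 ± 0.48), CDC27 (-2.01 ± 0.51), DEPP1 (-1.92 ± 0.31), IPO5P1 (-1.76 ± 0.35), FAM20A (-1.65 ± 0.26) and the kinase gene WNK4 (-1.64 ± 0.29). SLC2A10 (3.60 ± 0.82), SLAMF9 (3.52 ± 0.54), KRTAP3-1 (3.06 ± 0.33), TPSAB1 (2.45 ± 0.28), the TNF receptor gene TNFRSF1B (2.44 ± 0.42), CCN1, which encodes a matrix signalling protein (2.41 ± 0.41), C17orf49 (2.35 ± 0.39) and PLK3 (2.27 ± 0.45) rose. Metallothionein and metal-response genes passed camera with the preset and with an estimated correlation (adjusted p = 2.3e-05 and 0.016), with 5 of 14 higher and none lower (6 and 1 adjusted over the list alone). Immediate early genes (7 of 26 higher, 14 adjusted over the list alone) passed with the preset correlation (adjusted p = 4.9e-06) and had adjusted p = 0.26 with an estimated correlation. Histone mRNAs (1 of 18 higher, 4 adjusted over the list alone, median 0.33) had a camera adjusted p of 0.02 with the preset correlation and 0.35 with an estimated one. Calls by edgeR's quasi-likelihood test numbered 605, 387 higher and 218 lower. This count rested on single libraries: it was 4007 without weak-cloaked replicate 1, 114 or 126 without replicate 2 or 3, and 135, 194 or 395 without untransfected replicate 1, 2 or 3. A fit of these 6 libraries alone called 4 genes, DESeq2 called 2012, and with total-count scaling 33.8% of calls were higher in place of 64.0%.

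In cells given medium-cloaked mRNA, SPAG1 fell to 0.248 ± 0.0789 CPM (SD, n = 3). G6PC1 (-3.27 ± 0.36, SE), HPS6 (-3.44 ± 0.76) and FRAT1 (-2.79 ± 0.60) fell, as did SMC5 (-4.98 ± 1.52), the transcription factor gene NFIX (-3.46 ± 0.90), EDN1 (-3.37 ± 0.84) and the RNA polymerase I gene POLR1B (-3.22 ± 0.93), the last 4 with counts that differed 8-fold or more between replicates of a group. HSD17B7P2 (3.27 ± 0.66), SLAMF9 (3.20 ± 0.53), KRTAP3-1 (2.93 ± 0.33), NOS1AP (2.71 ± 0.56), CCN1 (2.63 ± 0.42), TENT5B (2.58 ± 0.57) and PLK3 (2.51 ± 0.45) rose, together with the glucuronosyltransferase gene UGT1A3 (3.25 ± 0.93), which shares exons with its family and was unstable between replicates. Of 26 cholesterol synthesis genes and SREBP2 targets 10 rose (12 adjusted over the list alone), and of 29 DNA replication genes 10 fell and 1 rose (15 and 2 adjusted over the list alone). With camera the adjusted p was 6.6e-06 and 0.00027 with the preset correlation, and adjusted p = 0.14 for both with an estimated correlation. Histone mRNAs (4 of 18 higher, none lower, median 0.55) had a camera adjusted p of 0.0099 with the preset correlation and 0.27 with an estimated one. Mitochondrially encoded mRNAs (4 of 13 lower, none higher) and leukocyte markers (3 of 15 higher, none lower) did not pass camera (adjusted p = 0.065 and 0.079). In all, 2524 genes passed edgeR's quasi-likelihood test, 1148 higher and 1376 lower, while with total-count scaling 18.3% were higher in place of 45.5%. Without untransfected replicate 1 or 2 the count was 1034 or 1140, without medium-cloaked replicate 1, 2 or 3 it was 1249, 785 or 819, and DESeq2 called 3794.

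In cells given strong-cloaked mRNA, SPAG1 fell to 0.252 ± 0.117 CPM (SD, n = 3), and G6PC1 (-2.99 ± 0.35, SE), MOCS3 (-2.64 ± 0.64) and MBTD1 (-2.54 ± 0.48) fell. The adhesion receptor gene ADGRL2 (-3.31 ± 0.76), PIF1 (-3.06 ± 0.91), ZNF362 (-2.88 ± 0.85) and EDN1 (-2.63 ± 0.81) fell with counts that differed 8-fold or more between replicates of a group. SLAMF9 (3.61 ± 0.54), HSD17B7P2 (3.08 ± 0.66), KRTAP3-1 (2.94 ± 0.33), TNFRSF1B (2.54 ± 0.42), TENT5B (2.50 ± 0.57), TPSAB1 (2.49 ± 0.28), NOS1AP (2.43 ± 0.56) and the glycodelin gene PAEP (2.42 ± 0.28) rose. Of 36 ribosomal protein genes 28 rose (32 and 1 lower adjusted over the list alone), and of 30 hypoxia and glycolysis genes 10 rose (12 adjusted over the list alone). Of 14 metallothionein and metal-response genes 6 rose (8 and 1 lower adjusted over the list alone). These 3 lists had an adjusted p in camera of 2.3e-13, 5.5e-06 and 8.8e-05 with the preset correlation, and adjusted p = 0.26, 0.26 and 0.028 with an estimated correlation. Histone mRNAs (4 of 18 higher, none lower, median 0.46) had a camera adjusted p of 0.017 with the preset correlation and 0.29 with an estimated one. Mitochondrially encoded mRNAs (3 of 13 lower, none higher) and leukocyte markers (3 of 15 higher, none lower) did not pass camera (adjusted p = 0.32 and 0.062). edgeR's quasi-likelihood test called 2776 genes, 1469 higher and 1307 lower, and with total-count scaling 18.4% were higher in place of 52.9%. The count was 1266, 948 or 1757 without untransfected replicate 1, 2 or 3, and 1497, 917 or 728 without strong-cloaked replicate 1, 2 or 3. DESeq2 called 4202.

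Of the genes called against untransfected cells, 308 were higher and 112 lower in all 4 comparisons, and no gene was called in opposite directions in any pair of them. Non-cloaked and strong-cloaked cells shared 653 higher and 389 lower calls, where independent lists would share 56.4 and 34.8. Unchanged groups simulated against the same controls shared 0 and 0. This follows from simulating no effect, so it cannot show how much the shared controls add to the overlap of called genes. Across 12057 genes, which are not independent replicates, the correlation of these fold changes was 0.837 against 0.506 simulated, and the covariance 0.328 against 0.068. The simulated values already hold the shared controls at the estimated dispersions, so the excess is what lies beyond that part. With different control libraries on the 2 sides, weak-cloaked replicates 2 and 3 correlated at 0.79 to 0.91 with the other transfected groups, over genes called in those groups. The 3 control libraries could not be split into parts of at least 2 libraries, so sharing beyond the simulated part was not tested for whole groups.

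The effect of cloaking itself was addressed by comparing each cloaked group with the non-cloaked group. Weak-cloaked cells differed from non-cloaked cells in SPAG1, which was higher by 5.43 ± 0.46 (SE) with an adjusted p of 0.00027 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It was high in 3 of 3 weak-cloaked libraries (8.68 to 16.2 CPM) and low in 3 of 3 non-cloaked ones (0.178 to 0.316 CPM). The next genes by p, BCORL1 (-1.17 ± 0.20), CPEB4 (2.95 ± 0.50), PIK3R5 (-1.73 ± 0.30) and NOS3 (-1.78 ± 0.34), did not pass. The hypoxia and glycolysis list, which includes genes of glucose use and oxygen response, had a median of 0.22 with no member called and none adjusted over the list alone. Its adjusted p was 0.024 with camera's preset correlation and adjusted p = 0.77 with an estimated correlation. SPAG1 was the 1 gene called, 721 genes had an unadjusted p below 0.05, and DESeq2 called 21. Without non-cloaked replicate 1 or weak-cloaked replicate 2, 2 genes were called.

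No gene was called between medium-cloaked and non-cloaked cells by edgeR's quasi-likelihood test. Among the genes of smallest p, none of which passed, were the mitochondrial carrier gene SLC25A30 (1.35 ± 0.21, SE), TBC1D10C (-1.53 ± 0.27), UBE2J2 (-0.88 ± 0.15) and ZEB1 (0.94 ± 0.17). Of the lists, the 13 mitochondrially encoded mRNAs had a median of -0.23, with none called and 1 lower adjusted over the list alone. The unfolded protein response had a median of 0.13 and the heat shock genes 0.16, with none of their 25 and 22 members called, nor adjusted over the list alone. Camera's adjusted p was 0.0017, 0.037 and 0.037 with the preset correlation, and adjusted p = 0.75 for all 3 with an estimated correlation. An unadjusted p below 0.05 was found for 1746 genes (9.5%), against 3.9% for weak and 3.6% for strong against non-cloaked cells. DESeq2 called 76. On principal component 2 the medium-cloaked libraries lay at -31.2 to -26.5 and the non-cloaked ones at -1.9 to 63.6. The lack of calls therefore does not show that these groups were alike. Without non-cloaked replicate 1 or medium-cloaked replicate 2, edgeR called 1 or 2 genes.

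Strong-cloaked and non-cloaked cells, the largest contrast in CR-3 treatment, had no called gene by edgeR's quasi-likelihood test either. The genes of smallest p, which did not pass, were CALCRL-AS1 (-4.40 ± 0.73, SE), the ubiquitin ligase gene RNF123 (-1.64 ± 0.29), MVB12A (2.32 ± 0.42), SVIL (3.33 ± 0.66, unstable between replicates) and SMG1P2 (1.68 ± 0.34). ISG15 differed by 0.13 ± 0.15 and MX1 by -0.38 ± 0.35, neither called. The hypoxia and glycolysis list had a median of 0.28, with log2 fold changes above 0 in 29 of 30 members and none called nor any when adjusted over the list alone. Hepatocyte products had a median of 0.11 and mitochondrially encoded mRNAs -0.15, also with no member called either way. Camera's adjusted p was 2.2e-07, 0.045 and 0.029 with the preset correlation, and adjusted p = 0.48, 0.48 and 0.53 with an estimated correlation. An unadjusted p below 0.05 was found for 663 genes (3.6%), and DESeq2 called 15. Without non-cloaked or strong-cloaked replicate 1, edgeR called 1 gene, and a fit of the 6 libraries alone called 2. The median 95% interval reached 0.62 on either side of a gene's log2 fold change, and 0.34 for genes above a log2 CPM of 5. In data simulated for this comparison, changes were placed only in genes with a mean log2 CPM of at least 1. Of these, 6.0% of 67 changes of 1.5-fold, 29.9% of 67 changes of 2-fold and 78.8% of 66 changes of 4-fold were recovered. Most differences of 2-fold or less between these groups could therefore have been missed.

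Across all 4 transfected groups, SPAG1 was the 1 gene called in edgeR's quasi-likelihood F test (adjusted p = 1.1e-05). SLC25A30, C17orf49, SH2D5 (unstable between replicates), CALCRL-AS1, BCORL1, TBC1D10C and NOS3 had the next smallest p and did not pass. An unadjusted p below 0.05 was found for 753 genes (4.1%), and DESeq2's likelihood ratio test called 55. Without non-cloaked replicate 2, weak-cloaked replicate 2, or medium-cloaked replicate 2 or 3, 2 genes were called.

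For a linear trend over the cloaking grades, from none to strong, no gene was called by edgeR's quasi-likelihood test. MVB12A (0.77 ± 0.13 per grade, SE), CALCRL-AS1 (-1.28 ± 0.23), RNF123 (-0.51 ± 0.09), SMG1P2 (0.55 ± 0.11) and the DNA repair gene MRE11 (0.38 ± 0.08) had the smallest p and did not pass. The median slope per grade was 0.06 for hypoxia and glycolysis, 0.04 for the unfolded protein response and -0.06 for mitochondrially encoded mRNAs, with no member called, nor adjusted over the list alone. Camera's adjusted p was 0.0011, 0.029 and 0.0091 with the preset correlation, and adjusted p = 0.54, 0.49 and 0.49 with an estimated correlation. An unadjusted p below 0.05 was found for 781 genes (4.2%), and DESeq2 called 20. Without non-, medium- or strong-cloaked replicate 1, edgeR called 1 gene.

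Between the strong and weak grades, SPAG1 was lower in strong-cloaked cells (log2 fold change -5.52 ± 0.46, SE; adjusted p = 0.00024 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), in 3 of 3 libraries against 3 of 3. CALCRL-AS1 (-4.06 ± 0.73), BCORL1 (1.05 ± 0.19), NOS3 (1.75 ± 0.34) and C17orf49 (-1.79 ± 0.38) came next and did not pass. Hepatocyte products, acute-phase genes, ribosomal protein genes and antigen presentation genes had medians of 0.15, 0.12, 0.10 and 0.17, with no member called, nor adjusted over the list alone. Camera's adjusted p was 0.008, 0.011, 0.011 and 0.018 with the preset correlation, and adjusted p = 0.79 for all 4 with an estimated correlation. Without weak-cloaked replicate 1, which stood apart, the ribosomal protein median was -0.04. SPAG1 was the 1 gene called, 571 genes had an unadjusted p below 0.05, DESeq2 called 11, and the fit of the 6 libraries alone called none. Leaving out strong-cloaked replicate 1 or 3, or weak-cloaked replicate 1 or 2, gave 4, 2, 2 or 3 calls.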

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

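The length and GC offsets, the comparison of shares between gene lists, the tests for a library swap, for an effect of the weak grade and for a dose with held-out controls, the shares of untransfected libraries, the tests of switching counts, the test of SPAG1's placement and a criterion on thinning were chosen only after the results were seen.

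SPAG1 drew attention because groups given the same reporter mRNA differed in it: weak-cloaked minus non-cloaked cells was 5.43 on the log2 scale and strong-cloaked minus weak-cloaked cells -5.52, with 597 to 2029 counts in each untransfected and weak-cloaked library and 11 to 24 in the other 9. Counts of 634 genes (3.4% of those tested) differed 8-fold or more between replicates of a group, with 100 or more counts in the higher library. Poisson counts drawn 20 times at the group means gave 0 such genes against the 634 observed, whose median highest count was 802. With the floor of 100 counts, a result of 0 was the likely outcome, so the draws cannot decide on sampling of few reads as the source. For these genes as a set, reads moved to an overlapping gene record are argued against. The median correlation with the overlapping gene was -0.01, and 15.4% of 356 such pairs lay below -0.3 against 16.6% of 3932 other pairs. SPAG1 itself was not among the 634 genes, so this explanation was not tested for it. Among 100 genes with an 8-fold gap between high and low libraries, SPAG1 was the 1 gene whose low libraries made up whole groups. Random placement gives 0.08 such genes (probability 0.0772), so a switch that fell on group lines by chance was not excluded. This probability pools 13 genes with 3, 6, 9 or 12 low libraries, where SPAG1 had 9. It therefore does not measure the placement of SPAG1 alone. The difference in SPAG1 between grades was called, but whether the weak grade caused it stays open.

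Weak-cloaked replicate 1 stood at 0.37 on a scale set by the mean shift of transfected libraries. Untransfected libraries, each set against the other 2 rather than all 3, stood at 0.22 to 0.28, so the baselines are not alike. Non-cloaked replicate 1 stood at 0.72 and the other transfected libraries at 0.88 or more. Replicate 1 was the lowest library of each transfected group (0.88 in medium- and 0.89 in strong-cloaked). An effect shared by replicate 1 libraries was therefore not excluded. Shallower sequencing is argued against, since thinning the other libraries to the total of weak-cloaked replicate 1 left the lowest at 0.71. The bound of 0.75 set beforehand was not met because non-cloaked replicate 1 stood at 0.72 before thinning. The argument therefore rests on the smallness of the fall, a criterion added after the result was seen. A swap with an untransfected library is argued against by the highest of those, 0.28, and an effect of the weak grade by its other replicates, at 1.03 and 1.16. Over 3165 genes its log2 changes correlated at 0.59 with those of the other transfected groups, but these genes were called with the same controls; on genes called without the control used (1285 to 2299), its correlations were 0.36 to 0.71 with slopes of 0.21 to 0.37, and on the 70, 440 or 557 genes called without a pair of untransfected libraries they were 0.36 to 0.71, against -0.25 to 0.02 between those libraries, which is consistent with a smaller dose of the same change, although genes are not independent replicates. Whether that dose was 1 share for all lists stays open, since the lower bound of epithelial-mesenchymal and TGF-beta targets, 0.31, lay above the upper bound of heat shock genes, 0.24, but non-overlapping pairs of lists also occurred in the other weak-cloaked replicates (5 in replicate 1, 19 in replicate 2 and 3 in replicate 3), and less uptake and handling stay open too.

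The shift between transfected and untransfected libraries followed transcript length and GC content, and genes called higher and lower differed by 8.65 points in median GC. With offsets for both, 4391 genes were called in place of 4242. The median of immediate early genes was 0.64 in place of 0.75, which argues against either trend as the whole cause for this list. The median of ribosomal protein genes was 0.31 in place of 0.43. Length was taken from the longest annotated transcript (7686 nt for RPL37), which need not be the one expressed. The offsets therefore cannot decide on length for ribosomal protein genes. The medians of p53 targets (0.14 in place of 0.32) and histone mRNAs (0.25 in place of 0.51) lost more than they kept. Called histone members went from 5 to 4 higher, with none lower in either fit. Called p53 members went from 7 to 10 higher and from 2 to 1 lower, so the median and the calls of that list point different ways. The trend stays open as the main cause for both lists. Splits of the 15 libraries argue against a chance division for the pooled comparison. The real split called 4242 genes, the highest other split 2, and 1 of 100 splits (the real one) reached as many. Other splits could mix transfected and untransfected libraries within a group, which widens the spread. The gap in calls therefore does not measure the effect. Particle, mRNA and handling were applied together, so which of them may lie behind the 4391 calls was not tested.

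For groups of 3 against 3, the 10 possible splits are too few for a share under 0.05. In fits of the compared libraries alone, the real split called 1013 genes for non-cloaked, 4 for weak-cloaked, 3590 for medium-cloaked and 3147 for strong-cloaked against untransfected cells, with 1 of 10 splits reaching as many in each, and the highest other splits called 1, 0, 2 and 2. Against non-cloaked cells, the real split called 1 gene for weak, 0 for medium and 2 for strong cloaking, with 6, 10 and 3 of 10 splits reaching as many and the highest other splits at 1, 3 and 4. Strong against weak cloaking called 0 genes, a count that 10 of 10 splits reached, with the highest other at 2. Chance could not be excluded for the number of calls in the F test among transfected groups (1 gene, highest other split 5, 32 of 100 splits as large). That count does not weigh the evidence for SPAG1 itself. The trend called 0 genes (highest other 4, 100 of 100 splits as large). Every split reaches a real count of 0. For the trend, medium against non-cloaked and strong against weak, the splits therefore cannot test chance.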

How the results depend on the processing

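Offsets for length and GC, total-count scaling and the removal of switching genes were chosen after the data were seen. Another normalization (RLE), both filter changes, the replicate block, non-robust estimation, total-count scaling and removal of switching genes kept all 11 counts of called genes within 1.5 times. DESeq2 called 2968, 2012, 3794 and 4202 genes for non-, weak-, medium- and strong-cloaked against untransfected cells, 21, 76 and 15 for weak, medium and strong against non-cloaked, 55 for the F test, 20 for the trend and 11 for strong against weak. Fits of the compared groups alone called 4 for weak-cloaked against untransfected, 2 for strong against non-cloaked, 3 for the F test, 1 for the trend and 0 for strong against weak. The offsets gave 1193 calls for weak-cloaked against untransfected, and 1530 together with the replicate block. Leaving out 1 library gave 119 to 1127 calls for non-cloaked, 114 to 4007 for weak-cloaked, 785 to 2089 for medium-cloaked and 728 to 1757 for strong-cloaked against untransfected, 2148 to 5938 for the pooled comparison, 1 to 2, 0 to 2 and 0 to 1 for weak, medium and strong against non-cloaked, 1 to 2 for the F test, 0 to 1 for the trend and 1 to 4 for strong against weak. List medians that reversed with total-count scaling, which shifts all genes, were ATF4 targets (-0.10, -0.02, -0.09 and -0.01 for the 4 groups against untransfected and -0.07 pooled), hypoxia (-0.06 non-cloaked, -0.07 medium), antigen presentation (-0.03 medium), NF-κB targets (-0.02 strong), hepatocyte products (-0.08 strong) and heat shock (-0.02 pooled). With 1 library left out, the hypoxia median in non-cloaked cells ran from -0.02 (without untransfected replicate 3) to 0.35, and the ribosomal protein median in strong against weak from -0.04 (without weak-cloaked replicate 1) to 0.17. Of 190 values of named genes, 103 kept direction and call under every alternative run; 8 lost their call with the block and 6 with the offsets, and of 164 values that use the untransfected libraries, 46, 45 and 32 lost their call without untransfected replicate 1, 2 and 3. Of 96 list calls, 93 were lost with an estimated correlation, 21 with the offsets and 0 with the block. The cause was not tested for any change that fewer libraries or the scaling does not itself explain. Pairing by replicate number was weak over all tested genes. Residuals of 30 same-number pairs correlated at -0.064 to 0.174 and of 60 other pairs at -0.137 to 0.113. Replicate 1 nonetheless stood lowest on principal component 1 in all 4 transfected groups (-7.8, -51.6, 17 and 11.9 for non-, weak-, medium- and strong-cloaked). An effect shared by replicate 1 libraries was therefore not excluded. Depth limits mostly genes of low count, since the spread between replicates sets the intervals.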

Other observations

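No test of an explanation was added in this part, and the lists were fixed beforehand.

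Genes of drug and bile acid metabolism went both ways in transfected against untransfected cells. Of 23 measured, 5 rose and 6 fell (7 and 6 adjusted over the list alone), and camera's adjusted p was 0.7. The bilirubin glucuronosyltransferase gene UGT1A1 rose by 1.99 ± 0.28 (SE, log2) and CYP1A2 by 1.34 ± 0.32, while the fetal cytochrome gene CYP3A7 (-2.03 ± 0.42) and CYP3A5 (-1.19 ± 0.24) fell. These families share sequence, so their counts are uncertain.

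Lipid genes outside cholesterol synthesis did not shift in a common direction. Of 26 PPAR targets and fatty acid oxidation genes, 7 rose and 5 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.45), with the lipid droplet gene CIDEC at 1.25 ± 0.15 and the coactivator gene PPARGC1A at -1.29 ± 0.20. Of 25 fatty acid synthesis genes and LXR targets, 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.45), with the sterol exporter gene ABCG8 at -1.74 ± 0.29 and AGPAT2 at 1.03 ± 0.12. PPARGC1A, a driver of gluconeogenic genes, fell together with G6PC1.

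Of 28 epithelial-mesenchymal and TGF-beta targets, 9 rose and 4 fell (12 and 6 adjusted over the list alone), with CCN1 at 2.23 ± 0.37, the repressor gene SNAI1 at 1.9 ± 0.30 and SKIL at -1.22 ± 0.28. The list's adjusted p in camera was 0.02 with the preset correlation and adjusted p = 0.16 with an estimated correlation.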
